A study of Mus musculus with 20 samples.

How the data were processed

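RNA from whole tumour fragments of 20 orthotopic caecum tumours was measured with 1 biotin-labelled sample per array, per the labels' protocols. The values are the deposited log2 values per probe set, made with RMA and the affy package per the submitters' processing notes, and their versions are not given in the sources used here. RMA corrects background, normalizes probes by quantiles and summarises them per probe set. Array medians ranged from 4.93 to 5.12 and maxima were nearly equal, as log2 RMA values are. Mice received 10 mg of galunisertib 2 times per day by gavage from day 11 to sacrifice in week 5, per the labels' protocols, and the treatment label LY was read as galunisertib.

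The table held 45141 probe sets. Of these 28898 had a single gene symbol in the platform annotation, 551 had several, 15588 had no gene named here and 104 were control probe sets, and 28689 single-symbol probe sets were matched by Entrez ID to current symbols. For each of 17097 genes the probe set with the highest mean over all arrays was used. Genes with a log2 value above 4.16, the 25th percentile of all values, on at least 2 arrays were tested, which left 15556. Probe sets without a single gene name were tested apart from them (12738 past the same filter). A probe set at or near that level gives little above background, so low genes were dropped from the tests rather than called absent.

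Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The effect over 5 lines was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) with the line as a block. All other comparisons came from a limma model with a mean for each of the 10 line-by-treatment groups and a shared spread, and the interaction was an F test over the 5 effects. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested at 0.05, and every adjusted p of a gene is limma's. Biological replicates were 2 per group, so the spread within a group came from all groups together. Plots were drawn with matplotlib 3.10.9.

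The 36 lists covered TGF-beta response, collagens and matrix, fibroblast, smooth muscle, enteric neuron and glia, pericyte, endothelial, immune cell types, interferon and MHC presentation, epithelial states, Wnt targets, proliferation, p53 targets, hypoxia, handling stress, sex-linked genes and markers of tissues near the caecum. They held 487 genes, of which 425 had a named probe set and 408 were tested. B2m, Tagln, Muc2, Lck, Thbs1 and Pmepa1 are list genes not analysed here. No member of a list was on another list. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. The calls named in the text are those of the preset correlation. An estimated correlation left 0 lists in any comparison. Scores per tumour, the mean over a list of each gene centred on its mean, were tested by exact permutation of treatment within lines.

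Named genes were, over 5 lines, up to 12 with the largest rise and 12 with the largest fall among those that passed with the same sign in each line, and elsewhere up to 5 and 5, or 5 of smallest p for the interaction. Gm, Rik and similar symbols were passed over. Where nothing passed, the 5 genes of smallest p were given as values. Up to 4 passing members of a list were named, else 2 of smallest p, and a fixed set of receptor, ligand, tumour and immune genes was always given. Further matrix genes in the text are members of the fixed list.

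The model was tested on simulated data with 15556 genes. Over 5 lines it recovered 60.3% of genes changed by 0.5, 98.4% by 1 and 100% by 2 on the log2 scale. For the LAKTP lines it recovered 45.5%, 89.2% and 100%, and for MTO68 9.21%, 49.3% and 88.7%. In 20 simulations of the 36 lists with no effect 2 lists were called, and a matrix list shifted by -0.7 was found in 20 of 20. Genes varied independently in these simulations, so they do not show how often correlated genes of a real list are called with no effect. A simulated effect was also the same in each line that carried it, and arrays did not differ in spread. The recovered shares thus need not hold for the real data, where Eln at -1.56 over 5 lines did not pass. No pair of arrays was identical.

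Alternatives were no filter and a stricter filter on dim genes, another probe set per gene, the mean of probe sets, median centring, quantile normalization of the deposited values, eBayes without trend, array weights, an epithelial covariate, omission of each array and each line, other treatments of the line, and an estimated correlation. The mean level of 7 hybridization control probe sets, the spread of an array's values and the fibroblast score as covariates, and the count of lists without each array in single lines, differences and control tumours, were added after seeing the data. Probe sets without a single gene name entered no list.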

Results

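Gene expression was measured in 20 caecum tumours of C57BL/6J mice, with 1 array per tumour. The tumours grew from 5 organoid (MTO) lines, and each line gave 2 tumours from control mice and 2 from mice treated with galunisertib, an inhibitor of the TGF-beta type I receptor kinase. The labels give MTO68 and MTO93 as parental lines of genotype LAKTP, MTO140 as an LAKTP line of type LiM, MTO54 as a parental LAKP line and MTO207 as a parental LAKT line. The labels do not spell out the letters of the genotypes. The 2 tumours of a group were biological replicates per the design text, and all 4 tumours of a line were hybridised on the same strip, so line and strip cannot be told apart while treatment was compared within strips. Whole tumour fragments were used, and the values describe tumour cells and host cells together. Median array values lay between 4.93 and 5.12 on the log2 scale, and the SD of an array's values lay between 1.46 and 1.83. The spread followed the mean level of 7 hybridization control probe sets, with r = -0.91 and rho = -0.92 over 20 arrays (permutation p = 1e-05 each, two-sided, the smallest the permutations can give) and r = -0.90 without the 2 farthest arrays. Within lines r was -0.95 in MTO68, -0.94 in MTO93, -0.98 in MTO140, 0.19 in MTO54 and -0.67 in MTO207 (n = 4 arrays each). Treated and control arrays differed by 0.05 in SD (exact permutation p = 0.303, two-sided). The number of arrays limited the precision of every comparison.

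**Figure D1:**
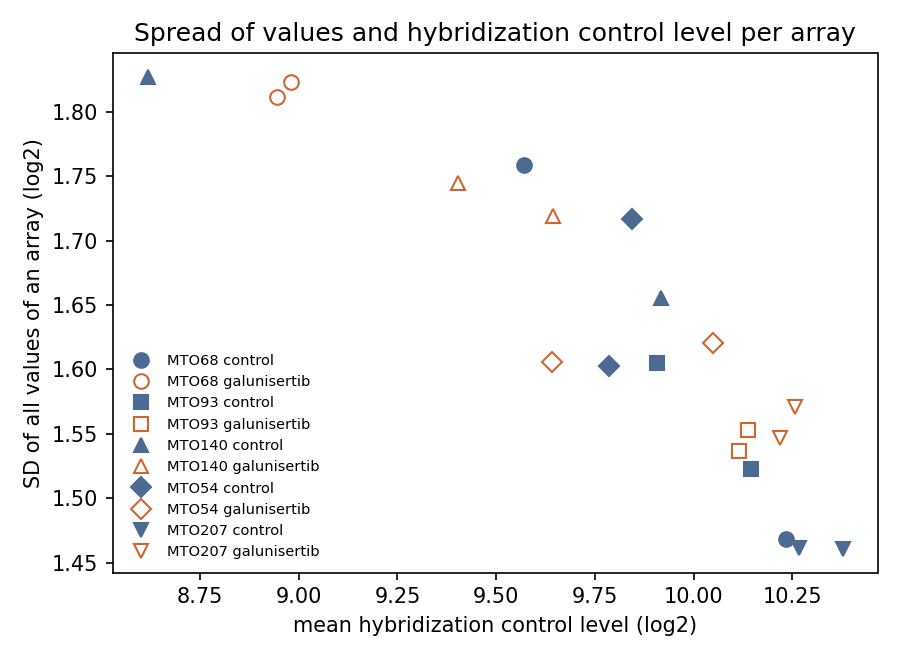
SD of all log2 values of an array against the mean log2 level of its hybridization control probe sets, with a symbol per line, filled for control and open for treated tumours. MTO68 control replicate 2 lies with the MTO207 control arrays at the lowest spread, apart from the other arrays of MTO68.

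Levels of a few receptor and tumour genes were compared between lines first. Tgfbr2, which encodes the TGF-beta type II receptor, had a mean log2 level of 7.97 ± 0.83 in MTO68, 8.00 ± 0.54 in MTO93, 8.37 ± 0.22 in MTO140, 7.71 ± 0.22 in MTO207 and 7.55 ± 0.67 in MTO54 (SD, n = 4 tumours each). Apc, a brake on Wnt signalling, lay between a mean of 7.16 ± 0.22 in MTO207 and 7.93 ± 0.56 in MTO68 (SD, n = 4). Lgr5, a marker of intestinal stem cells, was 7.30 ± 0.55 in MTO68, 5.99 ± 0.90 in MTO93 and between 5.30 and 5.56 in the other lines (SD, n = 4). Host cells carry intact alleles and a probe set can lie outside a deleted part, so these levels check no genotype. Trp53 was not analysed here.

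Treated and control tumours of all 5 lines were compared to ask what galunisertib does to the transcriptome of a whole tumour. Genes of the extracellular matrix were lower in treated tumours. All 21 measured members of the collagen and matrix list had lower mean levels, with a median log2 difference of -0.73, and the list fell against all other genes (camera adjusted p = 1.13e-25, two-sided). Eln, which encodes elastin, averaged 9.70 in 10 control tumours and 8.15 in 10 treated tumours, a log2 difference of -1.56 (SE 0.27), and was lower in 5 of 5 lines. Lox, an enzyme that crosslinks collagen and elastin, differed by -1.18 (SE 0.24), and Fn1, which encodes fibronectin, by -1.02 (SE 0.26). The fibrillar collagen genes Col1a1 and Col3a1 differed by -0.74 (SE 0.19) and -0.62 (SE 0.14). Adjusted over the list alone, 19 of the 21 matrix genes passed, against 0 when adjusted over all 15556 genes tested. The matrix call was lost with an estimated correlation (adjusted p = 0.119 with an estimated correlation).

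The list of fibroblast markers also fell, with a median of -0.46 and 13 of 14 members lower (adjusted p = 7.64e-11 with the preset correlation, adjusted p = 0.119 with an estimated correlation). Adjusted over the list alone, 9 fibroblast markers passed. Lum, which encodes the collagen-binding proteoglycan lumican, differed by -1.50 (SE 0.43), and the collagen VI gene Col6a2 by -0.54 (SE 0.15). Genes that respond to TGF-beta fell as a list, with 15 of 18 members lower, a median of -0.15 and a mean of -0.30 (adjusted p = 7.71e-06, and adjusted p = 0.208 with an estimated correlation). Adjusted over the list alone, 6 of them passed. The fall was uneven across members. Smad7 at 0.10 (SE 0.18), Bambi at 0.18 (SE 0.11) and Tgif1 at 0.04 (SE 0.20) were the members not lower, and Skil differed by -0.02 (SE 0.23). Adam12, a membrane metalloprotease, differed by -0.81 (SE 0.18) and Ltbp2, a microfibril protein related to the TGF-beta binding proteins, by -1.09 (SE 0.30). The ligand gene Tgfb3 differed by -0.72 (SE 0.23), Tgfb1 by -0.34 (SE 0.17) and Tgfb2 by 0.06 (SE 0.09). The receptor gene Tgfbr1 differed by -0.22 (SE 0.24) and Tgfbr2 by -0.22 (SE 0.23), and none of these 5 genes passed over all genes.

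Further lists of stromal cells were lower. Gut wall smooth muscle genes had a median of -0.36 with 10 of 10 members lower (adjusted p = 1.29e-05, and adjusted p = 0.230 with an estimated correlation). Des, the muscle intermediate filament gene desmin, differed by -0.45 (SE 0.19) and was higher only in MTO54. Pericyte genes had a median of -0.29 with 5 of 5 lower (adjusted p = 9.73e-04, and adjusted p = 0.119 with an estimated correlation). The potassium channel gene Kcnj8 differed by -0.54 (SE 0.12) and the adhesion gene Mcam by -0.29 (SE 0.10), and these were the 2 pericyte genes that passed when adjusted over the list alone. Endothelial genes had a median of -0.20 with 13 of 14 lower (adjusted p = 9.36e-07, and adjusted p = 0.208 with an estimated correlation). Plvap, which forms the diaphragms of fenestrated vessels, differed by -0.22 (SE 0.06) and the vessel sialomucin gene Emcn by -0.34 (SE 0.11), and 2 endothelial genes passed when adjusted over the list alone. Fry, whose p-value tests whether the genes of a list move on balance in a single direction without comparing them with other genes, gave adjusted p = 0.0221 for the matrix list and 0.0416 for both the fibroblast and the pericyte list.

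**Figure D2:**
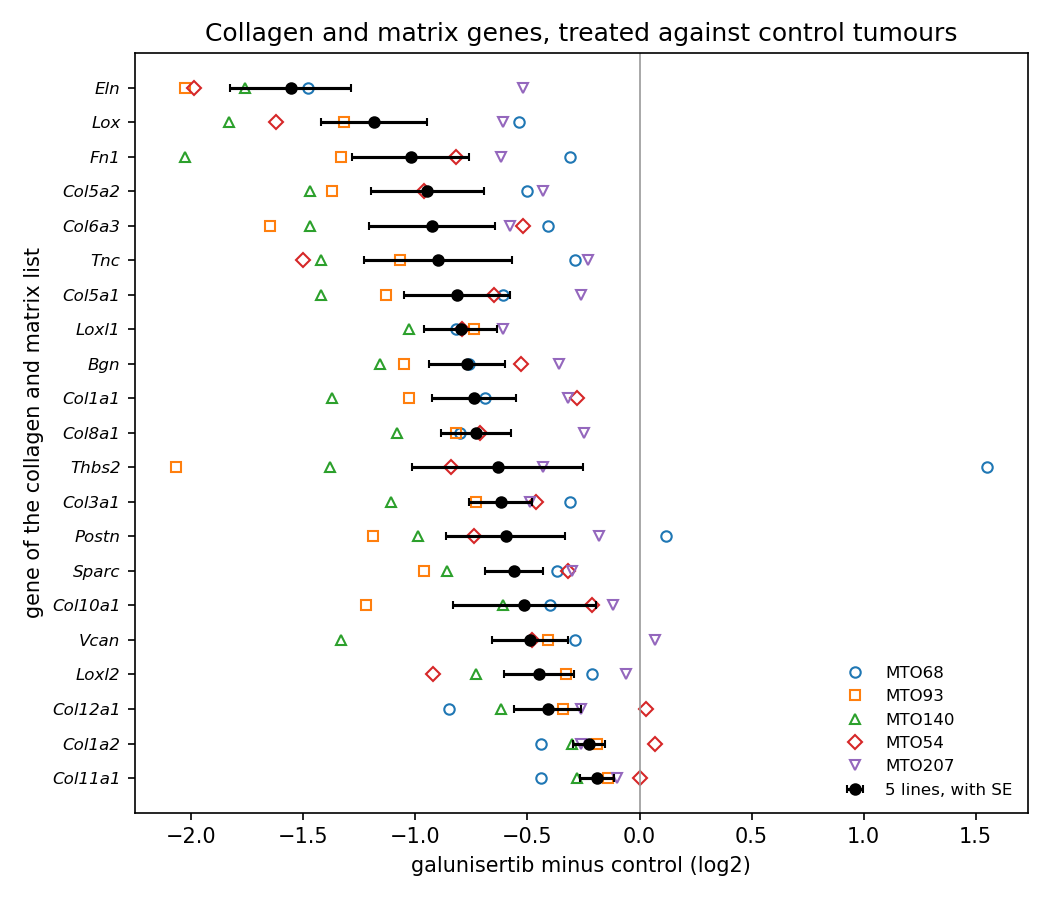
Treated minus control log2 difference of the 21 collagen and matrix genes, with black points and bars for the estimate over 5 lines and its SE and open symbols for each line (2 against 2 tumours). All 21 black points lie below 0, and Eln lies lowest at -1.56.

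Epithelial genes were higher in treated tumours, with a median of 0.26 and 17 of 17 members higher (adjusted p = 1.81e-06, and adjusted p = 0.334 with an estimated correlation). Krt8, a keratin of simple epithelia, averaged 11.1 in control and 11.4 in treated tumours, a difference of 0.24 (SE 0.08), and the tight junction gene Cldn7 differed by 0.31 (SE 0.11), each higher in 5 of 5 lines. Genes of colonocyte differentiation had a median of 0.52 with 15 of 15 higher (adjusted p = 0.00330, and adjusted p = 0.701 with an estimated correlation). The chloride-bicarbonate exchanger gene Slc26a3 differed by 1.20 (SE 0.56) and the brush border cadherin gene Cdhr5 by 0.57 (SE 0.29). Proliferation genes had a median of 0.18 with 20 of 21 higher (adjusted p = 2.76e-04, and adjusted p = 0.751 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 0.42 (SE 0.15) and the replication helicase gene Mcm5 at 0.38 (SE 0.17). Wnt target genes had a median of 0.25 with 10 of 11 higher (adjusted p = 0.0111, and adjusted p = 0.751 with an estimated correlation), led by Apcdd1 at 0.84 (SE 0.39) and Wif1 at 0.52 (SE 0.26), both of which encode inhibitors of Wnt signalling. The mean Wnt difference was 1.18 in MTO68, 0.60 in MTO207 and 0.18 in MTO54, but -0.44 in MTO93 and -0.15 in MTO140, and the list no longer passed without MTO68 control replicate 2, MTO68 galunisertib replicate 1 or MTO207 galunisertib replicate 2. The Wnt target median was 0.14 without MTO68 galunisertib replicate 1, that of proliferation genes 0.11 without MTO68 control replicate 2 and that of colonocyte genes 0.33 without MTO54 control replicate 1. The colonocyte list no longer passed without MTO93 control replicate 1. No gene of these 4 lists passed, over all genes or adjusted over the list alone.

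Interferon genes were higher as well. The type I interferon list had a median of 0.30 with 18 of 18 members higher (adjusted p = 8.07e-05, and adjusted p = 0.617 with an estimated correlation), with the transcription factor gene Irf7 at 0.52 (SE 0.18). The interferon-gamma list had a median of 0.35 with 14 of 15 higher (adjusted p = 0.00701, and adjusted p = 0.779 with an estimated correlation), with Cxcl9, a chemokine that attracts T cells, at 1.01 (SE 0.59). The list of MHC class I presentation had a median of 0.27 with 6 of 6 higher (adjusted p = 0.0111, and adjusted p = 0.7098 with an estimated correlation), with H2-T23 at 0.30 (SE 0.16). Neither the interferon-gamma nor the MHC class I list passed without MTO140 control replicate 1, MTO54 galunisertib replicate 1 or MTO207 control replicate 2, and the interferon-gamma list also failed without MTO140 galunisertib replicate 1 or MTO54 control replicate 2. Without MTO207 control replicate 2 the medians were 0.22 for the interferon-gamma and 0.16 for the MHC class I list, and without MTO68 control replicate 2 that of the type I interferon list was 0.20. Adjusted over the list alone, 0 genes of these 3 lists passed.

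Lists of immune cells did not pass. The median was 0.04 for T cells, 0.02 for cytotoxic lymphocytes, -0.10 for NK cell receptors, -0.04 for Treg and checkpoint genes, 0.05 for MHC class II presentation, 0.10 for B and plasma cells, -0.03 for neutrophils and 0.04 for mast cells. Dendritic cell genes had a median of -0.02, while their mean was 0.02 and the test pointed up. Macrophage genes had a median of -0.07 with 11 of 14 lower (adjusted p = 0.0819), and Trem2, a lipid receptor of macrophages, differed by -0.26 (SE 0.08). Cd8a, a marker of cytotoxic T cells, differed by -0.14 (SE 0.13), the protease gene Gzmb by 0.22 (SE 0.16), the T cell receptor zeta chain gene Cd247 by 0.32 (SE 0.11), the regulatory T cell factor Foxp3 by 0.05 (SE 0.05), and the checkpoint genes Pdcd1 and Cd274 by 0.04 (SE 0.05) and -0.03 (SE 0.13). Ifng and Tbx21 lay below the filter on dim genes and were not tested. Of the epithelial states, intestinal stem cell genes had a median of -0.05, goblet and enteroendocrine genes 0.04 and fetal-like and regenerative genes -0.19. The remaining lists that did not pass were p53 targets at 0.03, hypoxia and glycolysis at -0.01, enteric neuron and glia at -0.02, mesothelial at -0.09, adipocyte at -0.12, exocrine pancreas at -0.06, squamous keratinocyte at -0.06, blood at 0.05, handling stress at 0.04 and sex-linked genes at -0.03.

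**Figure D3:**
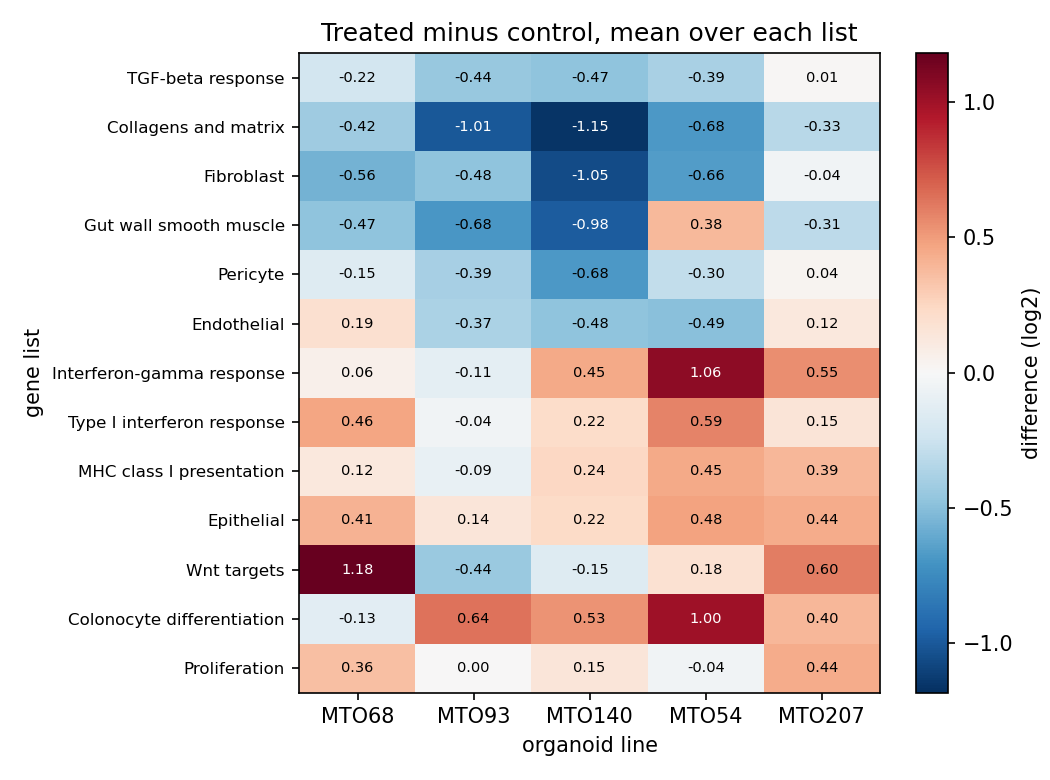
Treated minus control log2 difference of the mean of each list that passed over 5 lines, per organoid line (2 against 2 tumours), with blue for lower and red for higher in treated tumours. The collagen and matrix list is negative in each of the 5 lines, from -0.33 in MTO207 to -1.15 in MTO140.

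Among single genes, limma called 0 of 15556 over the 5 lines at an adjusted p of 0.05, while 1238 had an unadjusted p under 0.05 and 778 would be so by chance. The same 778 would be so by chance in every comparison below. The smallest adjusted p, 0.0862, was shared by Eln, Fam20a at -0.49 (SE 0.08), Spsb4 at -0.59 (SE 0.10), Fgf2 at -0.79 (SE 0.14) and Fstl3 at -0.64 (SE 0.12), each lower in 5 of 5 lines. Fgf2 encodes a fibroblast growth factor and Fstl3 an activin-binding protein. Without MTO68 control replicate 2, an array with few bright probe sets, 43 genes passed and all 43 were lower in treated tumours, 10 of them on the matrix list. Chosen after their values were seen, these included Eln at -1.72 (SE 0.24), Lox at -1.37 (SE 0.17), the metalloprotease inhibitor gene Timp3 at -1.28 (SE 0.19), Ccdc80 at -1.33 (SE 0.22), the lysyl hydroxylase gene Plod2 at -1.24 (SE 0.24), the Wnt inhibitor gene Sfrp1 at -1.22 (SE 0.22) and Col5a2 at -1.13 (SE 0.20). The matrix list (adjusted p = 0.0157 with an estimated correlation) and the fibroblast list (adjusted p = 0.0339 with an estimated correlation) then passed with an estimated correlation too. Without MTO54 control replicate 2, 20 genes passed, also all lower.

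Scores per tumour were tested without the model. The mean matrix score was lower in treated tumours in 5 of 5 lines, with a difference of -0.72 and an exact permutation p of 0.00334 (two-sided, labels permuted within lines, 7776 arrangements, smallest possible p 0.000257). After Benjamini-Hochberg adjustment over 36 lists the p was 0.0741, which did not pass. The fibroblast score differed by -0.56, lower in 5 of 5 lines (exact permutation p = 0.00412, adjusted 0.0741), and the epithelial score by 0.34, higher in 5 of 5 lines (exact permutation p = 0.0440, adjusted 0.317). Of the 36 lists, 0 passed this test, and 5 passed without MTO68 control replicate 2.

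**Figure D4:**
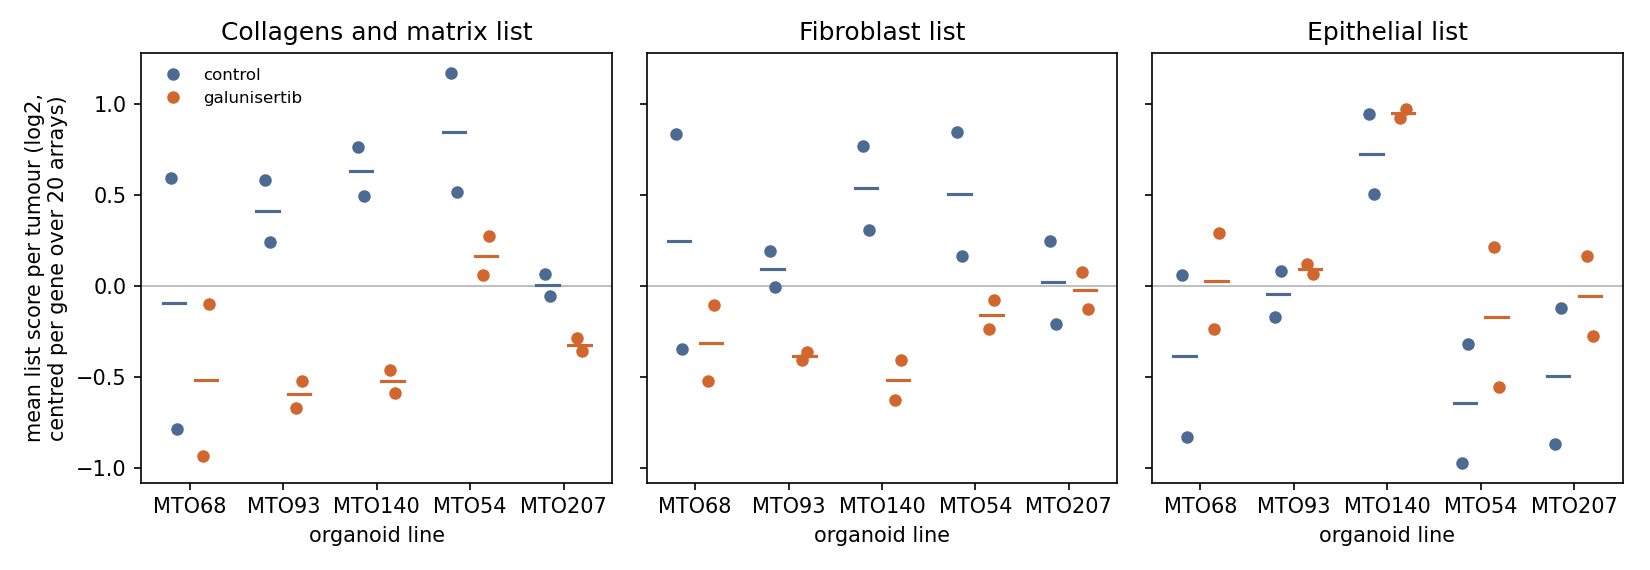
Mean score of the matrix, fibroblast and epithelial lists in each of the 20 tumours (log2, each gene centred on its mean over the arrays), with points for tumours and short bars for the mean of the 2 tumours of a group. The matrix score of MTO68 control replicate 2 is -0.78, below the other control tumours.

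The LAKTP lines MTO68, MTO93 and MTO140 were averaged to ask for the effect within a single genotype. Matrix genes fell by a median of 0.86 on the log2 scale with 21 of 21 members lower (adjusted p = 3.96e-22), and 16 passed when adjusted over the list alone. Eln differed by -1.76 (SE 0.34), the matrix glycoprotein gene Sparc by -0.73 (SE 0.16), the TGF-beta target Ccn2 by -0.98 (SE 0.24) and the growth factor receptor gene Pdgfrb, a mark of fibroblasts and pericytes, by -0.62 (SE 0.14). Smooth muscle genes fell by a median of 0.68 with 10 of 10 lower (adjusted p = 3.52e-08), with Des at -0.80 (SE 0.20), and 7 passed when adjusted over the list alone. Fibroblast genes had a median of -0.64 (13 of 14 lower, 8 passing adjusted over the list alone), pericyte genes -0.39 (4 of 5 lower), TGF-beta response genes -0.19 (15 of 18 lower) and endothelial genes -0.21 (13 of 14 lower). Intestinal stem cell genes had a median of -0.14 and fetal-like genes -0.26, while epithelial (0.20), type I interferon (0.17) and proliferation genes (0.15) were higher, which made 11 lists. None of the 11 passed with an estimated correlation (smallest adjusted p = 0.125 with an estimated correlation), while the matrix and fibroblast lists did without MTO68 control replicate 2 (adjusted p = 0.0207 with an estimated correlation for both). The type I interferon, proliferation, stem cell and fetal-like lists each passed in 14 of the 20 omissions of a single array, the epithelial list in 18, and the TGF-beta response and endothelial lists, lost without MTO68 control replicate 1, in 19. Without MTO68 control replicate 2 the type I interferon median was 0.02, the epithelial median 0.10 and the TGF-beta response median -0.33, without MTO140 control replicate 2 the proliferation median was 0.04, and without MTO93 control replicate 1 the fetal-like median was -0.08.

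In the LAKTP lines limma called 1 gene, 1700001L05Rik, at 0.50 (SE 0.07, adjusted p = 0.0387), named after its values were seen. Its difference was 1.40 in MTO68, -0.02 in MTO93 and 0.13 in MTO140, so the call came from MTO68. Below it stood Tbccd1 at 0.55 (SE 0.08), the gastric proton pump gene Atp4a at 0.94 (SE 0.15), the histone gene H4c9 at 0.68 (SE 0.11), Spsb4 at -0.63 (SE 0.10) and Kcnj8 at -0.58 (SE 0.09), each with adjusted p = 0.0522. At an unadjusted p under 0.05 there were 1479 genes. The count ranged from 0 without MTO93 control replicate 1 to 1336 without MTO68 control replicate 1, and moved over 1.5 times in 20 of 20 such omissions. Without MTO68 control replicate 2 it was 79 (15 higher and 64 lower), and quantile normalization of the deposited values gave 9 higher and 22 lower.

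In MTO68, treated tumours differed from control tumours in 312 genes (257 higher and 55 lower, limma). Cadps, a factor for the release of secretory granules, was 3.38 higher (SE 0.33, adjusted p = 2.09e-04), with levels of 4.91 and 3.60 in the control tumours and 8.18 and 7.09 in the treated tumours. This SE came from the spread of all groups together, and the Cadps levels of replicates lay far apart next to it. The SEs and p-values given for MTO68 may thus understate the spread within this line. The channel gene Pkd2l1 rose by 2.94 (SE 0.29), the neuronal pentraxin gene Nptx1 by 2.89 (SE 0.48), the retinol dehydrogenase gene Rdh9 by 2.90 (SE 0.60) and Apcdd1 by 3.08 (SE 0.66). Wnt target genes rose as a list, with a median of 1.03 and 11 of 11 higher (adjusted p = 0.00231, and adjusted p = 0.784 with an estimated correlation). Of these, 3 passed over all genes and 7 when adjusted over the list alone, among them Nkd1 at 1.21 (SE 0.27) and Lef1 at 1.12 (SE 0.27). The chemokine gene Ccl1 fell by 1.97 (SE 0.46), the secreted chaperone gene Clu by 1.62 (SE 0.31), the sodium channel gene Scn7a by 1.61 (SE 0.30), the leukocyte receptor gene Cd84 by 1.36 (SE 0.31) and Ccl27a by 1.22 (SE 0.28). The matrix list had a median of -0.44 with 19 of 21 lower (adjusted p = 0.0351, and adjusted p = 0.784 with an estimated correlation), and no longer passed without MTO68 control replicate 1 (median 0.18), MTO68 galunisertib replicate 1 or either MTO140 control array. These 2 lists became 9 without MTO68 control replicate 2, where the matrix median was -1.32 and the Wnt target median 0.67, with 9 of 11 members higher and 0 passing over all genes.

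The MTO68 calls rested on the control arrays. Control replicate 2 had an SD of 1.47 against 1.76 in control replicate 1 and 1.81 and 1.82 in the treated tumours, and correlated with control replicate 1 at r = 0.929 across probe sets, which are not independent, the lowest value of any group. Without control replicate 2, 40 genes were called (32 higher and 8 lower), 36 of them among the 312, and without control replicate 1, 8323 were. Cadps (2.72, adjusted p = 7.20e-04), Pkd2l1 (2.58, adjusted p = 0.00261) and Nptx1 (1.76, adjusted p = 0.0157) passed without control replicate 2, while Apcdd1 (1.72, adjusted p = 0.312), Rdh9 (2.36, adjusted p = 0.283), Clu (-1.35, adjusted p = 0.184) and Ccl1 (-1.93, adjusted p = 0.282) did not. Leaving out any single array moved the count over 1.5 times in 17 of 20 cases, between those extremes.

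In MTO93, matrix genes were lower in treated tumours by a median of -1.05 with 21 of 21 members lower (adjusted p = 1.44e-27), with Eln at -2.03 (SE 0.59) and Sparc at -0.96 (SE 0.28). TGF-beta response (-0.44), fibroblast (-0.47), smooth muscle (-0.79), pericyte (-0.33), endothelial (-0.23), stem cell (-0.17), Wnt target (-0.48) and handling stress genes (-0.19) were lower too. B and plasma cell genes were higher by 0.49 with 11 of 12 members higher (adjusted p = 1.38e-11), and mast cell (0.27), colonocyte (0.70) and goblet and enteroendocrine genes (0.47) were also higher. None of the 13 lists passed with an estimated correlation (smallest adjusted p = 0.147 with an estimated correlation). Without MTO93 control replicate 1 the colonocyte median turned to -0.04, that of goblet and enteroendocrine genes was 0.17, and these, the stem cell and the handling stress lists did not pass. That array also carried part of the B and plasma cell score difference (0.63, and 0.40 without it) and of the Wnt target median (-0.23 without it, and -0.20 without MTO93 galunisertib replicate 1), though both lists passed in every omission. The fibroblast median was -0.30 without MTO93 control replicate 1 and the endothelial median -0.14 without MTO93 control replicate 2. Pericyte genes did not pass without MTO93 control replicate 2 or MTO93 galunisertib replicate 1. The acute phase genes Saa1 and Saa2 differed by 3.56 (SE 0.68) and 3.94 (SE 0.84), and the neutrophil chemokine gene Cxcl5 by 3.64 (SE 0.78), the mast cell protease gene Mcpt9 by 0.47 (SE 0.10) and the B cell gene Ms4a1 by 0.77 (SE 0.18). Limma called 0 genes, with 169 at an unadjusted p under 0.05, where 778 would be so by chance.

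In MTO140, Kcnj8 fell from a mean of 5.24 ± 0.12 to 3.98 ± 0.06 (SD, n = 2 each), by 1.26 (SE 0.16, limma adjusted p = 0.0238), the only gene called. The treated mean lay below the filter level of 4.16, near background, so the fall may be understated. Matrix genes had a median of -1.16 with 21 of 21 lower (adjusted p = 3.30e-23), and 12 passed when adjusted over the list alone. Fn1 differed by -2.03 (SE 0.55), the proteoglycan gene Vcan by -1.33 (SE 0.33), Lum by -2.85 (SE 0.92) and the fibroblast transcription factor gene Prrx1 by -1.19 (SE 0.28). Fibroblast (-0.87), smooth muscle (-0.96), pericyte (-0.67), endothelial (-0.41), TGF-beta response (-0.27), macrophage (-0.34), stem cell (-0.38) and fetal-like genes (-0.42) were lower. Mast cell (0.23), T cell (0.18), cytotoxic lymphocyte (0.16), type I interferon (0.19), MHC class II (0.34), epithelial (0.23), colonocyte (0.44) and proliferation genes (0.15) were higher. The mast cell protease gene Mcpt1 differed by 2.56 (SE 0.81). None of the 17 lists passed with an estimated correlation (smallest adjusted p = 0.0582 with an estimated correlation, for pericytes), and their number was 9 without MTO140 control replicate 1 and 22 without MTO140 galunisertib replicate 2. Without MTO140 control replicate 1 the medians of MHC class II (-0.14) and T cell genes (-0.03) turned, that of TGF-beta response genes was -0.05, and these and the cytotoxic lymphocyte, type I interferon, macrophage, stem cell and fetal-like lists did not pass. Without MTO140 control replicate 2 the proliferation median turned to -0.15, that of colonocyte genes was 0.19, and these and the epithelial, type I interferon and fetal-like lists did not pass. The count of called genes moved when single arrays were left out. At an unadjusted p under 0.05 there were 565 genes, where 778 would be so by chance.

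In MTO54, the LAKP line, matrix genes had a median of -0.65 with 18 of 21 lower (adjusted p = 6.83e-08), and hypoxia and glycolysis genes -0.71 with 16 of 16 lower (adjusted p = 9.90e-12). Vegfa, the vessel growth factor induced by low oxygen, differed by -1.46 (SE 0.37). Fibroblast (-0.45), endothelial (-0.48), pericyte (-0.25), TGF-beta response (-0.28), p53 target (-0.26) and handling stress genes (-0.55) were lower. Interferon-gamma genes were higher by 0.92 with 14 of 15 members higher (adjusted p = 2.73e-05), with Cxcl9 at 2.45 (SE 1.35), and type I interferon genes by 0.57 with 17 of 18 higher (adjusted p = 1.26e-06). T cell (0.24), cytotoxic lymphocyte (0.31), MHC class I (0.41), dendritic cell (0.19), colonocyte (0.41), goblet and enteroendocrine (0.42) and smooth muscle genes (0.31) were higher. Slc26a3 differed by 3.30 (SE 1.25) and the galectin gene Lgals4, expressed in gut epithelium, by 2.97 (SE 1.12). None of the 17 lists passed with an estimated correlation (smallest adjusted p = 0.271 with an estimated correlation), and their number was 8 without MTO54 control replicate 1 and 21 without MTO54 galunisertib replicate 2. Without MTO54 control replicate 1 the TGF-beta response median turned to 0.02, those of fibroblast (-0.16), handling stress (-0.10), colonocyte (0.14) and goblet and enteroendocrine genes (0.16) shrank, and these and the smooth muscle, pericyte, T cell, cytotoxic lymphocyte, dendritic cell and p53 target lists did not pass. The matrix list passed without that array, with a median of -0.28, and the endothelial list with -0.19. Neither interferon-gamma nor MHC class I genes passed without MTO54 control replicate 2 or without MTO54 galunisertib replicate 1, where their medians were 0.43 and 0.14. Limma called 0 genes, with 444 at an unadjusted p under 0.05, where 778 would be so by chance. Smallest in p were Sh2d5 at -1.87 (SE 0.36), Kcnj8 at -0.83 (SE 0.16), Hmgn3 at -0.80 (SE 0.16), Pgap1 at -1.37 (SE 0.28) and Hopx at 1.99 (SE 0.43).

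In MTO207, the LAKT line, 4 lists passed and all were higher in treated tumours. The MTO207 control arrays had SDs of 1.46 and 1.46, the lowest of all arrays, against 1.57 and 1.55 in the treated arrays. These rises were thus not separated from array spread. Proliferation genes had a median of 0.38 with 19 of 21 higher (adjusted p = 4.95e-05), epithelial genes 0.44 with 17 of 17 higher (adjusted p = 6.53e-04), Wnt target genes 0.41 with 11 of 11 higher (adjusted p = 0.00162) and p53 target genes 0.23 with 15 of 19 higher (adjusted p = 0.0403). None passed with an estimated correlation (smallest adjusted p = 0.825 with an estimated correlation), and 18 lists passed with the preset correlation without MTO207 control replicate 2. The proliferation score difference of 0.44 was 0.28 without that array (median 0.26), and the list still passed. Epithelial genes did not pass without MTO207 control replicate 1 (median 0.16), Wnt target genes without MTO207 galunisertib replicate 2 (0.24), and p53 target genes without MTO207 control replicate 2 or MTO207 galunisertib replicate 1. The replication gene Mcm2 differed by 1.22 (SE 0.45), the ubiquitin ligase gene Rnf43, which dampens Wnt signalling, by 1.26 (SE 0.39) and the claudin gene Cldn3 by 1.06 (SE 0.40). The matrix score difference was -0.33, and fibroblast genes had a median of -0.09 while the test pointed up. Limma called 0 genes, with 1172 at an unadjusted p under 0.05, led by Serpina1b at -0.64 (SE 0.14), Icam4 at -0.58 (SE 0.13), Pglyrp2 at -0.46 (SE 0.10), Aprt at 0.80 (SE 0.18) and Crh at -0.57 (SE 0.13).

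Whether the effect of treatment differed between lines was tested with an F test over the 5 effects, which called 10 genes. These were Tbccd1 (F = 26.8, adjusted p = 0.0141), Atp4a (F = 22.8), Cadps (F = 21.4), Pkd2l1 (F = 21.2) and H4c9 (F = 19.9), and, named after their values were seen, 1700001L05Rik, Map2k6, Galnt18, Hs3st3b1 and Ccdc88a. Each had its largest difference in MTO68, from 0.82 for Ccdc88a to 3.38 for Cadps, and between -0.49 and 0.31 in the other 4 lines. The means over 20 arrays of Cadps (4.04), Map2k6 (3.72) and Galnt18 (3.98) lay below the filter level of 4.16. For such genes a difference near 0 outside MTO68 may only reflect probe sets near background. The F test also used the spread of all groups together, which may understate that within MTO68. The count was 2 without MTO93 control replicate 1 and 2807 without MTO68 control replicate 1. No matrix, fibroblast or TGF-beta response gene passed this test.

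The effect in MTO54 minus that in the parental LAKTP lines MTO68 and MTO93 compared the LAKP line with LAKTP lines. Smooth muscle genes were higher in this difference, with a median of 0.81 and 10 of 10 members above 0 (adjusted p = 3.30e-04), as were T cell (0.30), interferon-gamma (0.94) and goblet and enteroendocrine genes (0.58), while hypoxia and glycolysis genes were lower at -0.90 with 16 of 16 below 0 (adjusted p = 8.14e-07). None of the 5 lists passed with an estimated correlation (smallest adjusted p = 0.817 with an estimated correlation), and their number was 1, hypoxia and glycolysis, without MTO68 control replicate 1 and 12 without MTO93 control replicate 2. Without MTO54 galunisertib replicate 1 the interferon-gamma median was 0.45, and without MTO54 control replicate 1 the goblet and enteroendocrine median was 0.25 and the T cell median 0.16, and none of these passed. Myh11, the smooth muscle myosin gene, had a difference of 2.07 (SE 1.03) and Vegfa of -1.60 (SE 0.45). Limma called 0 genes, with 1245 at an unadjusted p under 0.05, led by Ccdc88a at -0.89 (SE 0.15) and H4c9 at -1.23 (SE 0.23), and 919 without MTO68 control replicate 1.

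The effect in MTO207 minus that in MTO68 and MTO93 passed for 11 lists. Given the low spread of the MTO207 control arrays, these differences were not separated from array spread either. Matrix genes were higher in this difference, with a median of 0.36 and 20 of 21 above 0 (adjusted p = 7.64e-04), as were fibroblast (0.52), TGF-beta response (0.22), endothelial (0.19), interferon-gamma (0.71), MHC class I (0.33), epithelial (0.22), stem cell (0.57), fetal-like (0.23) and proliferation genes (0.29). B and plasma cell genes were lower at -0.38 with 11 of 12 below 0 (adjusted p = 0.00540). None of them passed with an estimated correlation (smallest adjusted p = 0.647 with an estimated correlation), and their number was 1, stem cell genes, without MTO68 control replicate 1, where the matrix median was 0.04, and 21 without MTO68 control replicate 2. Without MTO207 control replicate 2 the medians of interferon-gamma (-0.64) and MHC class I genes (-0.10) turned and proliferation genes (0.09) did not pass, and without MTO207 control replicate 1 the epithelial median turned to -0.14 and stem cell genes did not pass. Ccn2 had a difference of 1.29 (SE 0.50), the stem cell factor gene Sox9 of 1.10 (SE 0.41) and Tbccd1, which led by p, of -1.14 (SE 0.17, adjusted p = 0.156). Limma called 0 genes, with 463 at an unadjusted p under 0.05, where 778 would be so by chance.

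The effect in MTO140 minus that in MTO68 and MTO93 passed for 0 of 36 lists and 0 genes by limma. At an unadjusted p under 0.05 there were 746 genes, where 778 would be so by chance. Leaving out MTO68 control replicate 1 raised the counts of called genes and lists. Kcnj8 had a difference of -1.02 (SE 0.20), Sec16b of -0.63 (SE 0.12), Ccdc88a of -0.77 (SE 0.15), Slco3a1 of -1.38 (SE 0.28) and the endothelial receptor gene Tek of -0.61 (SE 0.22), and none passed.

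The control tumours were compared between lines to ask how a tumour of the LiM type or of another genotype differs from parental LAKTP tumours. Each of these 3 comparisons set 2 tumours against the same 4 control tumours of MTO68 and MTO93, so part of any likeness between them comes from those 4. A single line stood for its type or genotype, together with its strip, and MTO140 organoids were injected under the caecal serosa while the other lines were transplanted as pieces of subcutaneous tumours.

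In MTO140 control tumours 152 genes differed (115 higher and 37 lower). The platelet chemokine gene Ppbp was 4.16 higher (SE 0.51), the haemoglobin genes Hbb-b2 and Hba-a1 3.82 (SE 0.64) and 3.66 (SE 0.63), Cxcl5 3.62 (SE 0.68) and the GPI anchor remodelling gene Pgap1 3.37 (SE 0.24, adjusted p = 1.06e-05). Bex1 was lower at -5.83 (SE 0.59), the transcription factor gene Prox1 at -3.30 (SE 0.35), Wfdc18 at -2.78 (SE 0.39), Wif1 at -2.42 (SE 0.41) and Ccdc3 at -2.24 (SE 0.28). The parental lines themselves stood apart in several of these, with Prox1 at 9.22 in MTO68, 5.70 in MTO93 and 4.16 in MTO140, and Wif1 at 7.96, 3.43 and 3.28. Wif1 in MTO93 and MTO140 lay below the filter level of 4.16 and Prox1 in MTO140 at it. The sizes of these differences are thus limited by background. Epithelial genes were higher by a median of 0.99 with 17 of 17 members higher (adjusted p = 2.11e-04), among them the intestinal transcription factor gene Cdx2 at 1.90 (SE 0.38, adjusted p = 0.0362), and hypoxia and glycolysis genes by 0.87 with 16 of 16 higher (adjusted p = 4.34e-05). Colonocyte (1.58), goblet and enteroendocrine (1.21), handling stress (0.82), pericyte (0.70), matrix (0.38) and endothelial genes (0.38) were higher too. T cell (-0.43), cytotoxic lymphocyte (-0.56), NK receptor (-0.53), Treg and checkpoint (-0.19), MHC class II (-0.80), MHC class I (-0.49), dendritic cell (-0.25), type I interferon (-0.27) and Wnt target genes (-0.65) were lower. The control arrays had SDs of 1.83 and 1.66 in MTO140, 1.76 and 1.47 in MTO68 and 1.60 and 1.52 in MTO93. These list differences were thus not separated from array spread. None of the 17 lists passed with an estimated correlation (smallest adjusted p = 0.566 with an estimated correlation), and the Wnt call was lost without MTO68 control replicate 1 or MTO140 control replicate 2. Without MTO68 control replicate 2 the medians were 0.07 for matrix, 0.47 for epithelial, 0.51 for hypoxia and -0.37 for cytotoxic lymphocyte genes, and the matrix, NK receptor, Treg and checkpoint and dendritic cell lists did not pass. Without MTO140 control replicate 1 the MHC class II median was -0.37 and that of dendritic cell genes -0.06, and these and the NK receptor and Treg and checkpoint lists did not pass. Without MTO140 control replicate 2 the matrix, pericyte, type I interferon, MHC class I and goblet and enteroendocrine lists did not pass. The count was 8 without MTO140 control replicate 1, the array with the lowest hybridization control level, and 6352 without MTO68 control replicate 1, and quantile normalization of the deposited values gave 91 higher and 49 lower. Without MTO68 control replicate 2 it was 156 (69 higher and 87 lower).

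In MTO54 control tumours 207 genes differed (139 higher and 68 lower). The kinase gene Prkg2 was 3.70 higher (SE 0.36, adjusted p = 5.11e-04), Ppbp 3.45 (SE 0.51), the GABA receptor subunit gene Gabrp 3.24 (SE 0.41), the retinaldehyde dehydrogenase gene Aldh1a3 3.14 (SE 0.41) and Slc4a11 3.10 (SE 0.50). Bex1 was lower at -6.39 (SE 0.59), the immunoglobulin transporter gene Pigr at -3.36 (SE 0.62), Tmem45b at -3.28 (SE 0.65), the sodium pump gene Atp1b1 at -3.22 (SE 0.74) and Prox1 at -3.17 (SE 0.35). Type I interferon genes were lower by a median of -1.28 with 18 of 18 members lower (adjusted p = 8.27e-15), and 4 passed over all genes and 16 when adjusted over the list alone. Type I interferon scores of the control tumours were 1.31 and 0.30 in MTO68, -0.02 and -0.42 in MTO93 and -1.08 and -0.90 in MTO54. The parental lines thus stood apart here too, and the p-value does not measure the spread between lines. Usp18 was lower at -2.46 (SE 0.49), Zbp1 at -2.16 (SE 0.47), Stat2 at -1.73 (SE 0.34) and Irf7 at -1.54 (SE 0.34). Endothelial (0.48), pericyte (0.74), matrix (0.64), TGF-beta response (0.71), fibroblast (0.43), hypoxia (0.52), fetal-like (0.38), p53 target (0.27) and handling stress genes (1.11) were higher, with Vegfa at 1.86 (SE 0.32, adjusted p = 0.0106) and Notch3, a receptor of mural cells, at 1.00 (SE 0.21, adjusted p = 0.0333). Interferon-gamma (-1.34), MHC class I (-0.92), MHC class II (-0.69), T cell (-0.23), cytotoxic lymphocyte (-0.27), Treg and checkpoint (-0.14), mast cell (-0.30), Wnt target (-0.79), colonocyte (-1.20), goblet and enteroendocrine (-0.60) and sex-linked genes (-0.63) were lower. None of the 21 lists passed with an estimated correlation (smallest adjusted p = 0.133 with an estimated correlation), and 12 passed without MTO54 control replicate 1. Without it the medians were 0.31 for TGF-beta response, 0.07 for fibroblast, 0.01 for p53 target, -0.66 for colonocyte and -0.20 for goblet and enteroendocrine genes, and these lists did not pass. Pericyte (0.49), endothelial (0.28), matrix (0.32) and fetal-like genes (0.24) shrank without it too, and the fetal-like list did not pass. Without MTO68 control replicate 2 the medians were 0.26 for matrix, 0.24 for hypoxia, 0.45 for TGF-beta response, 0.13 for fibroblast, 0.09 for p53 target and -0.11 for cytotoxic lymphocyte genes, and the last 3 of these lists did not pass. Interferon-gamma (-0.74) and MHC class II genes (-0.36) did not pass without MTO54 control replicate 2. The fibroblast and mast cell lists each passed in only 7 of the 20 omissions of a single array. The count was 23 without MTO54 control replicate 1, 1540 without MTO68 control replicate 1, and 321 (133 higher and 188 lower) without MTO68 control replicate 2.

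In MTO207 control tumours 6 genes differed and all were lower, namely Prox1 at -3.01 (SE 0.35, adjusted p = 0.00793), the desaturase gene Scd1 at -2.33 (SE 0.37), Ccdc3 at -2.06 (SE 0.28), Ceacam10 at -1.79 (SE 0.24), Gpld1 at -1.74 (SE 0.22) and, named after its value was seen, the growth factor binding protein gene Igfbp4 at -0.98 (SE 0.16). Scd1 stood at 9.46 ± 0.77 in MTO68, 7.40 ± 0.61 in MTO93 and 6.10 ± 0.18 in MTO207 (SD, n = 2 each). Wnt target genes were lower by a median of -0.70 with 11 of 11 members lower (adjusted p = 7.53e-04), as were stem cell (-0.39), interferon-gamma (-0.85), type I interferon (-0.49) and MHC class I genes (-0.64), and enteric neuron and glia genes were higher at 0.28. Wnt target scores of the control tumours were 1.31 and 0.29 in MTO68, -0.03 and -0.37 in MTO93 and -0.58 and -0.36 in MTO207, and the Wnt call held in 20 of 20 omissions of a single array. None of the 6 lists passed with an estimated correlation (smallest adjusted p = 0.856 with an estimated correlation), and their number was 3 without MTO68 control replicate 2 and 9 without MTO207 control replicate 1. Without MTO207 control replicate 2 the medians of interferon-gamma (0.31) and type I interferon genes (0.05) turned and that of MHC class I genes was -0.02, so these 3 calls rested on that tumour. The count was 0 without MTO93 control replicate 1 and 5079 (2553 higher and 2526 lower) without MTO68 control replicate 2, and quantile normalization of the deposited values gave 35 higher and 104 lower. At an unadjusted p under 0.05 there were 2880 genes.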

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

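The test of dilution by tumour epithelium, the covariates for hybridization control level, array spread and fibroblast score, the separate reading without MTO68 control replicate 2 and the count of lists without each array for comparisons other than those over 5 lines and in the LAKTP lines were chosen only after the results were seen.

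The hybridization control level of MTO140 control replicate 1 was 8.62, against 9.57 in the next of the 10 control tumours, and the Wnt target score of MTO68 control replicate 1 was 1.31, against 0.29 in the next. These came from 78 tests of a sample lying far from its group, and chance flags about 1 in 20 groups. The effect of treatment differed between lines in 10 genes, each with its largest difference in MTO68. By a test of the difference itself, the effect differed from that in MTO68 and MTO93 for 5 lists in MTO54 and for 11 lists in MTO207, all with the preset correlation and 0 with an estimated correlation. Leaving out a single array moved the 5 to between 1 (without MTO68 control replicate 1) and 12 (without MTO93 control replicate 2), and the 11 to between 1 (without MTO68 control replicate 1) and 21 (without MTO68 control replicate 2). Of the 12738 probe sets without a single gene name, 1 passed over 5 lines, at -1.07 (SE 0.14, limma adjusted p = 0.00387).

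Collagen and matrix genes were lower in treated tumours, with a score difference of -0.72 (95% interval -1.10 to -0.34). Array brightness was argued against as the whole cause, since the difference was -0.79 (-1.13 to -0.45) with the hybridization control level as covariate. Without the single array MTO68 control replicate 2 the difference was -0.84 (-1.14 to -0.54). That control array had a matrix score of -0.78, below the other control tumours, and so worked against the difference. Leaving it out had to enlarge the difference, so this was no test of the array as its cause. For a larger share of tumour epithelium that dilutes all host cells alike, the matrix score minus the mean of 7 immune lists differed by -0.73 (-1.17 to -0.30). The immune mean itself differed by 0.02 (-0.12 to 0.15). T cell and NK receptor scores were 0.38 and 0.41 in MTO68 control replicate 2, an array of low spread. They were -0.43 and -0.64 in MTO140 control replicate 1, the array of widest spread. The immune mean may thus follow array spread rather than the share of host cells, so this test cannot decide on dilution. Fewer fibroblasts as a whole stayed open as a candidate source, because with the fibroblast score as covariate the difference was -0.19 (-0.45 to 0.08). The fibroblast list genes Dcn and Col6a1 averaged 9.15 and 9.01 in control and 8.42 and 8.22 in treated tumours (n = 10 each). While 0 of the 14 fibroblast genes are on another list, several, such as Lum, Col6a1 and Col6a2, encode matrix proteins themselves. The covariate thus overlaps the matrix score in kind and cannot tell fewer fibroblasts from lower matrix expression. The whole tumours were not sorted.

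The 312 genes called in MTO68 were weighed next. Of them, 89.1% were nearer to the treated mean in control replicate 1 than in control replicate 2, so an array of low spread in the control group may account for part of the calls. An effect of galunisertib against both control tumours stayed open, because its test decides nothing: the median share of the difference left against control replicate 1 was 0.777, but the genes had been called with that array, which favours a high share. For a tumour of another line under the label of MTO68 control replicate 2, its correlation with MTO68 was 0.508 over 200 line-marking genes. This exceeded the best other line by 0.487 but lay below the other MTO68 arrays, at 0.927 to 0.950. All 20 of 20 arrays lay nearest to their own line, the MTO93 control arrays by only 0.023 and 0.066. Line-marking genes cannot be told apart from strip-marking genes, so a tumour of another line on the same strip was not excluded.

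Other splits of treatment within lines, 100 with the real one, were run for the main counts. For called genes over 5 lines the real count was 0 (limma, 1238 genes at an unadjusted p under 0.05) and the highest other 0, so all 100 of 100 had to reach it and the comparison says nothing about chance. Over 5 lines 25 of 100 gave as many shifted lists (13 real, 21 in the highest other). In the LAKTP lines 42 of 100 gave as many called genes (1 real, 102 in the highest other) and 44 of 100 as many shifted lists (11 real, 19 in the highest other). Chance could not be excluded for the counts of lists or for the genes in the LAKTP lines. The split with 102 genes may point to a structure of the samples other than treatment, which was not tested.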

How the results depend on the processing

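The covariates for hybridization control level, array spread and fibroblast score were chosen only after the data were seen. Of the named gene values under the alternatives, 3303 kept direction and side of the threshold and 71 passed newly with the same direction. Another 51 changed direction without passing, and 0 changed direction and passed. With 0 genes called over 5 lines in the main setting, no named gene could lose a pass. Of the values of the 13 called lists in 39 settings, all with the preset correlation, 464 kept both, 42 no longer passed and 1 reversed. Wnt targets passed in 27 of 39, interferon-gamma response in 30, MHC class I presentation in 32, colonocyte differentiation in 34, proliferation in 37 and each other called list in 38. Medians of the matrix list ran from -0.87 to -0.20, and it no longer passed with the fibroblast score as covariate. An estimated correlation, not among the 39, lost all 13 calls. The values given next are counts of called genes unless lists are named, and the cause was not tested. With an estimated correlation 0 lists shifted (limma camera, 7 at an unadjusted p under 0.05). Without a filter on dim genes LAKTP gave 8 and MTO140 2, and with a stricter filter LAKTP gave 4, MTO140 0 and the interaction 6. With the probe set of largest variance LAKTP gave 2 and MTO54 1, and with the mean of probe sets LAKTP gave 6 and MTO207 minus parental 1. Median centring gave 2 in LAKTP and 0 in MTO140. Quantile normalization of the deposited values gave 56 for the galunisertib effect over 5 lines (2 higher, 54 lower), 31 for the galunisertib effect in LAKTP lines, 150 for the galunisertib effect in MTO68, 376 for MTO54 against parental LAKTP, control tumours, 139 in MTO207 controls and 2 list scores. Without trend LAKTP gave 0, MTO140 0 and the interaction 3. Array weights gave 116 over 5 lines (25 higher, 91 lower), 13 in MTO68, 4 in MTO93, 0 in MTO140, 144 for the galunisertib effect in MTO207, 2 in MTO140 controls, 16 in MTO54 controls, 0 in MTO207 controls and 0 for the interaction. With the epithelial score as covariate LAKTP gave 4, MTO68 116, MTO140 0, MTO140 controls 10 and list scores 3, and the colonocyte list reversed to -0.12. Without line MTO68 the count was 10 over 5 lines and 31 in LAKTP. Without line MTO140 it was 12 in LAKTP, with 4 LAKTP lists, and without line MTO54 it was 2 over 5 lines and 0 in LAKTP, with 8 lists. Without line MTO207 LAKTP gave 0, and the mean of the 5 line effects gave 2. With the hybridization control level as covariate there were 9 over 5 lines, 16 in LAKTP, 17 in MTO68, 2 in MTO140, 1 in MTO54, 15 in MTO140 controls, 2 in MTO207 controls, 0 for the interaction and 5 list scores. With array spread there were 166 over 5 lines (7 higher, 159 lower), 185 in LAKTP, 62 in MTO68, 11 in MTO140, 80 in MTO140 controls, 517 in MTO54 controls, 2 for the interaction and 6 list scores. With the fibroblast score 3 lists shifted and 3497 genes passed over 5 lines (1765 higher, 1732 lower). Leaving out each array in turn, where a lone tumour is assumed to vary like the other groups, gave 0 to 43 over 5 lines, 0 to 1336 in LAKTP, 40 to 8323 in MTO68, 0 to 1 in MTO93, 0 to 26 in MTO140, 0 to 9 in MTO54 and 0 to 0 in MTO207. The ranges were 0 to 919 for MTO54 minus parental, 0 to 12 for MTO207 minus parental and 0 to 63 for MTO140 minus parental. They were 8 to 6352 for MTO140 controls, 23 to 1540 for MTO54 controls, 0 to 5079 for MTO207 controls, 2 to 2807 for the interaction, 11 to 18 for lists, 8 to 15 for LAKTP lists and 0 to 5 for list scores. The lowest and highest omissions for MTO68 were control replicate 2 and control replicate 1. Genes near background give small differences on arrays, so effects on dim genes are limited by signal.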

Other observations

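The Y-linked genes Kdm5d and Eif2s3y had mean log2 levels of 5.31 and 5.58 in MTO54 (n = 4), against 6.11 to 6.43 and 6.38 to 7.50 in the other 4 lines (n = 4 each). No test of these line means was run, though the sex-linked list, which holds both genes, passed as lower in MTO54 control tumours with the preset correlation.

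Across 15556 genes the effect of treatment in MTO68 correlated with that in MTO207 at r = 0.61 and with that in MTO54 at r = -0.30, and the effects in MTO93 and MTO140 correlated at r = 0.46, with r between -0.20 and 0.34 for the other pairs of lines. In both MTO68 and MTO207 an array or arrays of the control group had the lowest spread of the line, and the first principal component (46.2% of variance) followed array spread at r = -0.98, so these values were not separated from array spread. Genes are not independent, and no test was run.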
